A study of Mus musculus with 16 samples.

How the data were processed

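Gene expression was measured in early B-lineage cells of BALB/c mice. Each of 4 bone marrow sorts pooled cells of 16 female adult mice, and each of 4 fetal liver sorts used the embryos of a litter at gestation day 16, on average 8 embryos. Every sort gave 1 sample of fraction A (Fr.A) and 1 of fraction B/C (Fr.B/C), in the Hardy scheme the pre-pro-B stage and the pro-B stage that follows it. Total RNA (100 ng) was amplified and hybridised to 16 dual-colour Agilent whole mouse genome arrays, each against a common reference of total RNA from 6 cell lines. The sample was in Cy5 on the arrays numbered 1 and 3 and in Cy3 on those numbered 2 and 4, per the labels. The 4 groups of 4 arrays were bone marrow Fr.A, bone marrow Fr.B/C, fetal liver Fr.A and fetal liver Fr.B/C. The number of arrays limits the precision of every value.

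The deposited scanner files were written by Feature Extraction 8.5.1.1. Per the file headers they hold for each spot a mean signal and a background signal of both dyes as intensity. They also hold processed signals, which are intensity values background-subtracted, spatially detrended and dye-normalized by linear and lowess steps, per the file headers. The scanner's own log ratio is log10 of Cy5 over Cy3, per the file headers. The authors also deposited 1 table of log2 ratios for the series, whose values run as sample over reference. It was centred near 0, with array medians from -0.00726 to 0.0201, and correlated across probes with the ratios computed here at r = 0.930 to 0.951. The method behind that table is not given in the sources used here. The submitters' processing notes name limma, with no version.

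Mean and background signals were read for this work, the background was corrected with normexp and an offset of 50, and each array was normalized by loess in limma 3.58.1 under R 4.3.3. The offset compresses the fold changes of dim genes. Every log2 ratio was turned to sample over reference. Control spots had weight 0 in loess and were left out afterwards, as were spots that the scanner software marked as non-uniform or population outliers. Saturated spots were kept. Spots of the same probe were averaged. A probe was kept if it was well above background in the sample's channel on at least 3 of the 4 arrays of any group and had a usable value on at least 12 arrays, which left 27522 of 41174 probes. Of all probes, 27296 were named, 22072 of them through their RefSeq accession, 135 through another listed accession, 3129 through a RIKEN clone, 230 through a LOC number, and 1200 and 530 through the symbol in the description, found or not found in the reference table of symbols. A further 7 matched several genes and 13871 stayed unnamed. Each gene was represented by its kept probe of highest mean brightness, which gave 21620 genes or unnamed transcripts to test, 14365 of them with a symbol. Symbols alone were used, with no coordinates.

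A limma model with the 4 group means and a dye term was fitted to all 16 arrays (11 residual degrees of freedom), with empirical Bayes and Benjamini-Hochberg adjustment, and a gene passed at an adjusted p under 0.05. All adjusted p-values of genes come from this limma model unless another is named. The comparisons were fetal liver against bone marrow in Fr.A and in Fr.B/C, Fr.B/C against Fr.A in bone marrow and in fetal liver, and the difference between the last pair, called the interaction. Errors are the model's standard errors (SE). For a probe not well above background on any array of a group, or saturated on all of them, the fold is a lower bound. It sets the bright group's mean sample channel, after loess and Aquantile, against the dim group's mean of the higher of the probe's own signal and the lowest signal among probes well above background on that array, or, where lower, it is the fold of the log ratios less the same step up to that signal.

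The groups, comparisons, named-gene rule, gene lists and the other settings to try were fixed before the data were examined. For each comparison of 2 groups the rule took the 8 highest and 8 lowest changes among genes that passed, whose groups did not overlap, that had a plain symbol and that were well above background on all 4 arrays of the higher group, with 5 and 5 for the interaction. It added up to 4 members per gene list with the smallest adjusted p, the sex-linked genes, and in each comparison Lin28a, Lin28b, Arid3a, Hmga2, Igf2bp1, Igf2bp2, Igf2bp3, Dntt, Rag1, Rag2, Ebf1, Pax5 and Il7r. Lin28a and Pax5 had no probe that met the filter. The text names a part of the genes the rule took. Of 28 lists, 27 were tested as sets (the sex-linked genes served to check labels), with camera at a preset inter-gene correlation of 0.01, camera with an estimated correlation, and fry, adjusted over the 27 lists of a comparison. The fry PValue tests whether members move on balance one way and its Mixed value whether they change in either direction, and neither compares a list with other genes. A list's count of genes is given over all genes tested and adjusted over the list alone.

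The functions behind these tests were tested on simulated data made from the real arrays' means and spread, with 200 of 21620 genes changed in fetal liver Fr.A. These simulated arrays were independent, without the likeness within array sets described below, so the shares hold for independent arrays only. For fetal liver against bone marrow in Fr.A, 46.3%, 94.0% and 100% of the genes changed by 0.5, 1 and 2 on the log2 scale were recovered, beside 8 false calls. For Fr.B/C against Fr.A in fetal liver the shares were 43.3%, 91.0% and 100% with 7 false calls, and for the interaction 16.4%, 76.1% and 97.0% with 6.

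Pairing was checked on deviations from the group means. Fr.A and Fr.B/C arrays of the same number, which the labels trace to the same sort, deviated together (r across genes = 0.421 to 0.519 in bone marrow and 0.247 to 0.383 in fetal liver). They were taken as pairs in the fits with the sort as a block. For the fraction comparisons and the interaction, the fits with the replicate number as a block did so too. Between the tissues that block was an effect of the number shared by bone marrow and fetal liver, which does not keep these pairs. The main model did not take them as pairs, and its p-values ignore the pairing. Bone marrow and fetal liver share no animals, and their arrays of the same number gave r = -0.263 to 0.148 in Fr.A and 0.276 to 0.480 in Fr.B/C. An r of the latter size therefore does not by itself show a shared sort. The arrays numbered 1 and 2 of a group also resembled each other, as did those numbered 3 and 4. These are called array sets below, and fits with the set as a block, with each set averaged, and with each set averaged plus a set term shared by the groups were added after seeing the data. Counts from the last of these (2 values per group, 3 residual degrees of freedom) stand beside the main counts. In simulated data with no changed gene and a set effect common to the groups, p under 0.05 was reached by 7.69% to 7.87% of genes in the main model, and by 5.00% to 5.24% in that fit. With a set effect of its own in each group (set correlation 0.57) the shares were 14.0% to 14.6% in the main model, with 27 to 119 false calls, and 5.02% to 5.31% with each set averaged.

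The other settings fixed in advance were the processed signals, no background subtraction, median centring, Aquantile, the deposited table, other filters on dim probes, no dye term, the replicate number as a block, the sort as a random block, only the arrays compared, array weights, other probe rules, trended and robust empirical Bayes, stricter thresholds, a single dye orientation, each array left out in turn, scan session as a block, and the other list tests. Scaling and quantile normalization between arrays were added after seeing that Aquantile moves no log ratio.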

Results

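Gene expression was profiled in Fr.A and Fr.B/C cells sorted from adult bone marrow and from fetal liver, 4 arrays per group and 16 in all, each against the same reference RNA. The series title names 2 proteins, Lin28b and Arid3a, in fetal B lymphopoiesis, and the arrays compare fetal with adult cells at each of these stages. The median sample signal of an array ranged from 71.2 to 162 (intensity), 52.9% to 68.3% of probes were well above background, and 0.221% to 0.624% were saturated. Arrays correlated with each other at r = 0.614 to 0.973 across genes, which are not independent replicates. The 2 leading principal components held 41.6% and 29.5% of the variance.

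In Fr.A, the fetal liver cells were marked by the heterochronic Lin28b genes, all 6 of which were higher than in bone marrow. Lin28b, an RNA-binding protein that blocks let-7 maturation, had a log2 fold change of 3.40 ± 0.15 (SE; n = 4 and 4 arrays, adjusted p = 3.92e-10). It was not well above background on any bone marrow array, and the difference was at least 10.4-fold on the reported probe. Its 3 probes gave changes from 0.22 to 3.40. Igf2bp1 (3.40 ± 0.14, at least 10.2-fold), Igf2bp2 (2.96 ± 0.11) and Igf2bp3 (4.23 ± 0.22), RNA-binding proteins of fetal tissues, rose with it. So did the chromatin protein Hmga2 (2.03 ± 0.20) and the transcription factor Arid3a (1.94 ± 0.12, adjusted p = 1.56e-08). At the other end stood Dntt, which encodes the terminal transferase that adds nucleotides at V(D)J junctions, with -8.81 ± 0.46 (n = 3 bone marrow and 4 fetal liver arrays). Its probe was saturated on the bone marrow arrays, so the difference was at least 309-fold (adjusted p = 4.04e-09). Over all probes the changes ran from 2.07 to 4.23 for Igf2bp3, 2.03 to 3.15 for Hmga2 and -9.04 to -3.72 for Dntt.

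As a list, the 6 Lin28b genes passed the set test in Fr.A (adjusted p = 4.57e-12 and, with an estimated correlation, 0.00121). Because the title names Lin28b and Arid3a, that list is not independent evidence of its direction, and all 6 members also stand in the list of let-7 targets. Of 32 measured let-7 targets, 17 were higher, 4 lower and 11 did not pass (19 and 4 adjusted over the list alone; adjusted p = 1.47e-08). The 17 include all 6 Lin28b genes. The cyclin gene Ccnd1 rose by 2.34 ± 0.08. Of 16 imprinted growth genes, 7 were higher and 3 lower (9 and 3 adjusted over the list alone; adjusted p = 0.00011), among them Grb10 (2.25 ± 0.15), Peg3 (1.74 ± 0.10) and the cell cycle inhibitor Cdkn1c (1.59 ± 0.10). Of 33 mitotic genes, 25 were higher and none lower (27 adjusted over the list alone; adjusted p = 1.86e-14), including Ube2c (1.34 ± 0.11) and the spindle factor Tpx2 (1.18 ± 0.09). These 3 lists kept their calls with an estimated correlation (adjusted p = 0.00112, 0.00687 and 0.00883). Of 31 S-phase genes 8 were higher and none lower, with the same count adjusted over the list alone (adjusted p = 0.00488, and adjusted p = 0.149 with an estimated correlation). Of 39 oxidative phosphorylation genes 10 were higher and none lower, 7 adjusted over the list alone (adjusted p = 8.27e-05, and adjusted p = 0.0965 with an estimated correlation). Among single genes with the highest changes were Fgd5 (3.03 ± 0.13), the cyclooxygenase gene Ptgs1 (3.03 ± 0.20) and the muscle troponin Tnni2 (3.02 ± 0.09).

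Interferon response and antigen presentation genes were lower in fetal liver Fr.A. Of 38 interferon response genes 34 fell and none rose, also when adjusted over the list alone (adjusted p = 1.42e-20, and 0.000537 with an estimated correlation). Examples were Tgtp1 (-4.02 ± 0.14, and -0.64 on its other probe), Ifi44 (-3.51 ± 0.15), the antiviral synthetase Oas1a (-1.77 ± 0.09) and the immunoproteasome subunit Psmb8 (-1.49 ± 0.08). MHC class II genes fell in 11 of 12 cases (adjusted p = 7.07e-11, and 0.0076 with an estimated correlation), with the same count adjusted over the list alone. The invariant chain Cd74 fell by 2.89 ± 0.11 and H2-DMa by 1.93 ± 0.12. The class I genes H2-D1 (-4.31 ± 0.20), H2-Q7 (-4.18 ± 0.16) and H2-T23 (-3.97 ± 0.16) were also among the most lowered, but class I genes share much sequence, and their values are not separable by gene here.

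Lymphoid genes in Fr.A moved less uniformly. Of 16 genes of later B-cell stages, 7 were lower and 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.00546, and 0.0278 with an estimated correlation). The chemokine receptor Cxcr5 fell (-1.96 ± 0.15) while the adaptor Bank1 rose (1.44 ± 0.17, and 0.44 on its other probe). Of 25 B-lineage specification genes, 7 fell and 2 rose (8 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.242). Within it the transcription factor Ebf1 was lower by a small margin (-0.56 ± 0.12, adjusted p = 0.00292) and the adaptor Blnk by a larger one (-1.997 ± 0.17). The Ebf1 call was lost with the array sets averaged (adjusted p = 0.0711) and with Cy5 alone. Of 15 V(D)J recombination genes, 4 were higher and 2 lower (adjusted p = 0.956), and the recombinase genes Rag1 (-0.21 ± 0.13, adjusted p = 0.235) and Rag2 (0.05 ± 0.10, adjusted p = 0.779) did not pass, nor did the interleukin 7 receptor Il7r (-0.17 ± 0.19, adjusted p = 0.576). The probes of Rag1 gave changes from -0.21 to 0.35.

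Markers of other cell types differed between the Fr.A sorts of both tissues. Of 20 erythroid genes, 15 were higher in fetal liver, among them the anion exchanger Slc4a1 (2.41 ± 0.34), the transcription factor Klf1 (2.63 ± 0.45) and the blood group gene Rhd (3.08 ± 0.67, adjusted p = 0.00261). The Rhd call was lost with the array sets averaged (adjusted p = 0.0918) and with either dye alone, and its log2 ratios were 0.05 and -0.03 on fetal liver arrays 1 and 2 but 2.61 and 2.74 on arrays 3 and 4. Those of Klf1 parted in the same way (1.95 and 2.00 against 3.55 and 3.73). The 1 erythroid member counted as lower, Hbb-bt, was saturated on all fetal liver arrays and has no direction. Over the list alone 18 erythroid genes were higher and 1 lower (adjusted p = 3.07e-07, but adjusted p = 0.234 with an estimated correlation). NK cell markers were lower in 10 of 16 cases (adjusted p = 1.64e-05, and 0.0278 with an estimated correlation) and T-lineage markers in 10 of 18 (adjusted p = 0.00205, and adjusted p = 0.149 with an estimated correlation). None of either list was higher, and both counts were the same adjusted over the list alone. The cytotoxic granule gene Nkg7 fell by 3.14 ± 0.14 and Thy1 by 1.89 ± 0.16 (its other probe gave -0.61). Ly6d, a surface protein of lymphoid progenitors, fell by 3.49 ± 0.20. Of 22 myeloid markers 10 were lower and 4 higher (12 and 5 adjusted over the list alone), for example lysozyme Lyz2 (-2.05 ± 0.21), and the list did not pass (adjusted p = 0.138). It did so with the array sets averaged and a set term (adjusted p = 0.00689) and with the replicate number as a block (0.016). Basophil and mast cell markers (4 of 9 lower, adjusted p = 0.11) passed with that block (0.0465), but not with the array sets averaged and a set term.

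Immediate early stress genes fell in 10 of 22 cases and rose in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.0466, but adjusted p = 0.622 with an estimated correlation). That call was lost without bone marrow array 3 (0.149) or 4 (0.0962) or fetal liver array 1 (0.0990). The other lists did not pass in Fr.A. Higher and lower members numbered 3 and 3 of 8 for immunoglobulin and plasma cell genes (adjusted p = 0.947), 6 and 7 of 26 for stem cell genes (0.956), 0 and 3 of 18 for Polycomb genes (0.594), 7 and 2 of 18 for glycolysis (0.138), and 1 and 3 of 40 for ribosomal proteins (0.21). They numbered 4 and 11 of 30 for cytokine receptors (adjusted p = 0.242), 5 and 5 of 15 for plasmacytoid dendritic cell markers (0.956), 2 and 1 of 8 for megakaryocyte markers (0.158), 2 and 2 of 9 for hepatocyte markers (0.756), and 1 and 2 of 11 for stromal and endothelial markers (0.749).

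Across all genes, 6402 of 21620 differed between the tissues in Fr.A, 2667 higher and 3735 lower in fetal liver, among them 311 higher and 694 lower by at least 2-fold. The deposited table gave 2028 and the processed signals 2312 genes at least 2-fold apart. In 5672 genes (26.2%, against 2.86% by chance for independent arrays) the arrays of both tissues did not overlap. Arrays of a set resembled each other, so the share by chance is higher than 2.86% and was not estimated. With each array set averaged and a set term, 3934 genes passed, 3844 of them among the 6402. Median centring in place of loess gave 4041 genes, of which 22.9% were higher, against 41.7% in the main analysis. Bone marrow and fetal liver arrays were scanned in different sessions, so tissue and session cannot be told apart, and with the session as a random block 5558 genes passed.

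**Figure D1:**
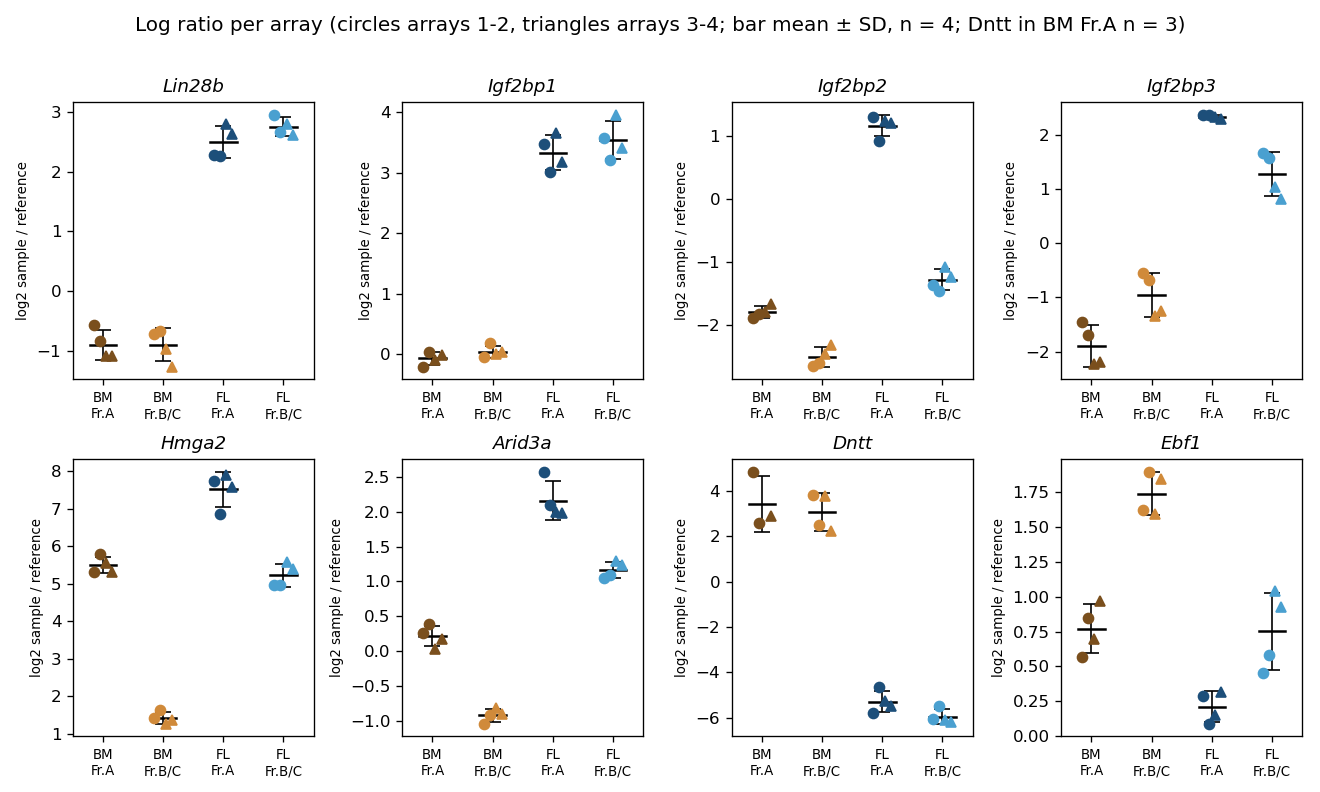
Log2 sample over reference of heterochronic Lin28b genes, Dntt and Ebf1 in the 4 groups, with a circle for each of the arrays 1 and 2, a triangle for each of the arrays 3 and 4, and bars at the mean ± SD (n = 4 arrays, 3 for Dntt in bone marrow Fr.A). Fetal liver lay above bone marrow for Arid3a by 1.94 in Fr.A and 2.09 in Fr.B/C. In bone marrow Lin28b and Igf2bp1 were not well above background and Dntt was saturated, so the distances drawn for them are not measured sizes.

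In Fr.B/C the same 6 Lin28b genes were again higher in fetal liver. Lin28b differed by 3.66 ± 0.15 (SE; n = 4 and 4 arrays, adjusted p = 1.16e-10, at least 12.4-fold) and Igf2bp1 by 3.50 ± 0.14 (at least 10.7-fold). Hmga2 (3.81 ± 0.20), Igf2bp3 (2.23 ± 0.22), Arid3a (2.09 ± 0.12, adjusted p = 5.65e-09) and Igf2bp2 (1.22 ± 0.11) followed. Probes gave changes from 0.35 to 3.66 for Lin28b, 0.84 to 3.81 for Hmga2, 0.89 to 2.48 for Igf2bp3 and -9.03 to -3.70 for Dntt. Dntt was lower by at least 369-fold (-9.03 ± 0.42, adjusted p = 9.56e-10), again with a probe saturated in bone marrow. The list passed with both correlations (adjusted p = 1.62e-10 and, estimated, 0.00205).

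Let-7 targets, the 6 Lin28b genes among them, were higher in 18 of 32 cases and lower in 2 (18 and 3 adjusted over the list alone; adjusted p = 1.14e-07, and 0.00176 with an estimated correlation). Imprinted growth genes were higher in 8 of 16 and lower in 1, with the same count adjusted over the list alone (adjusted p = 0.000216, and 0.00818 with an estimated correlation). They included Grb10 (2.33 ± 0.15), Peg3 (1.86 ± 0.10) and the growth factor receptor Igf2r (1.60 ± 0.11). Mitotic genes rose in 11 of 33 cases and none fell, also adjusted over the list alone (adjusted p = 0.000306, but adjusted p = 0.199 with an estimated correlation), with Plk1 at 0.90 ± 0.11 and Aurka at 0.69 ± 0.09. The Aurka call was lost with Cy3 alone. The highest single changes included the ribosomal protein paralogue Rpl39l (3.87 ± 0.10, and 0.58 on its other probe), Fgd5 (3.54 ± 0.13) and Ptgs1 (3.40 ± 0.20).

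Genes of the B lineage were lower in fetal liver Fr.B/C. Of 25 B-lineage specification genes 13 fell and none rose, also adjusted over the list alone (adjusted p = 3.05e-07, and 0.00979 with an estimated correlation), among them Ebf1 (-0.99 ± 0.12, adjusted p = 2.41e-05) the surface gene Cd72 (-1.94 ± 0.18) and the kinase Blk (-1.03 ± 0.12). Genes of later B-cell stages fell in 8 of 16 cases and rose in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.00187, and 0.0162 with an estimated correlation), for example Ms4a1, which encodes CD20 (-0.74 ± 0.10). V(D)J recombination and end joining genes fell in 7 of 15 cases and rose in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.00244, but adjusted p = 0.106 with an estimated correlation). The end joining genes Lig4 (-1.29 ± 0.20) and Xrcc6 (-1.27 ± 0.15) and the recombinase genes Rag1 (-0.63 ± 0.13, adjusted p = 0.00161) and Rag2 (-0.32 ± 0.10, adjusted p = 0.0287) were among them. Over its probes Rag1 gave changes from -0.69 to -0.29. The Rag1 call was lost with the array sets averaged (adjusted p = 0.0536), with either dye alone and on arrays 1 and 2 alone. The Rag2 call was lost with the array sets averaged or as a random block, with or without a set term, with either dye alone and on arrays 1 and 2 alone. It was also lost with the processed signals, no background subtraction, scaling between arrays, trended and robust empirical Bayes and the scan session as a random block, and without bone marrow array 2, 3 or 4 (adjusted p = 0.0654, 0.0507 and 0.0754) or fetal liver array 1, 2 or 4 (0.0534, 0.0632 and 0.0808). Il7r did not pass (-0.33 ± 0.21, n = 3 fetal liver and 4 bone marrow arrays, adjusted p = 0.262) except with the replicate number as a block (-0.41, adjusted p = 0.00816).

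Interferon response genes fell in 35 of 38 cases and 1 rose (36 and 1 adjusted over the list alone; adjusted p = 5.94e-27, and 0.000149 with an estimated correlation). Tgtp1 fell by 4.87 ± 0.14 (its other probe gave -0.43), Ifi47 by 3.12 ± 0.12, Oas1a by 2.76 ± 0.09 and Psmb8 by 1.67 ± 0.08. MHC class II genes fell in 11 of 12 cases, also adjusted over the list alone (adjusted p = 6.31e-10, and 0.00979 with an estimated correlation), with H2-DMa at -1.96 ± 0.12 and Cd74 at -1.61 ± 0.11. The class I genes H2-Q7 (-4.70 ± 0.16), H2-T23 (-4.60 ± 0.16) and H2-D1 (-4.56 ± 0.20) and the progenitor gene Ly6d (-3.36 ± 0.20) fell as in Fr.A. The oestrogen receptor gene Esr1 was not well above background on any fetal liver array and was lower by at least 19.4-fold (-4.30 ± 0.12).

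Erythroid markers were higher in 14 of 20 cases and none was lower (17 and 1, the saturated Hbb-bt, adjusted over the list alone; adjusted p = 3.23e-06, but adjusted p = 0.297 with an estimated correlation), with Rhd at 3.55 ± 0.67, Slc4a1 at 3.25 ± 0.34 and Klf1 at 2.52 ± 0.45. With the array sets averaged the calls of Rhd (adjusted p = 0.0674) and Klf1 (0.0556) were lost, as they were with Cy5 alone and that of Rhd with Cy3 alone. The log2 ratios of Rhd were again apart, at -0.07 and 0.23 on fetal liver arrays 1 and 2 against 2.54 and 2.60 on arrays 3 and 4. Those of Klf1 were 1.88 and 2.04 against 3.70 and 3.65. Hepatocyte markers were higher in 4 of 9 and lower in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.0342, adjusted p = 0.119 with an estimated correlation, 0.0577 with the replicate number as a block, and 0.0525 to 0.0695 without bone marrow array 3 or 4 or fetal liver array 1 or 2). Myeloid markers fell in 9 of 22 cases and rose in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.00187, but adjusted p = 0.419 with an estimated correlation), including Lyz2 (-2.37 ± 0.21). T-lineage markers fell in 6 of 18 and rose in 1, also adjusted over the list alone (adjusted p = 0.0342, but adjusted p = 0.334 with an estimated correlation), including the kinase Lck (-1.33 ± 0.12). The T-lineage call was lost without bone marrow array 3 (0.0692) or fetal liver array 1 (0.0695). NK cell markers fell in 2 of 16 and rose in 1 (adjusted p = 0.0887). Immediate early genes fell in 8 of 22 and rose in 1 (11 and 3 adjusted over the list alone; adjusted p = 0.0228, but adjusted p = 0.433 with an estimated correlation), a call lost without bone marrow array 3 (0.0692) or 4 (0.0690). Glycolysis (adjusted p = 0.0578), oxidative phosphorylation (0.106) and basophil and mast cell markers (0.0578) did not pass. They did with the array sets averaged and a set term (0.0498, 0.0498 and 0.0408). Glycolysis also passed without that term (0.0482), and the basophil list with the replicate number as a block (0.0355). Glycolysis passed without bone marrow array 1 (0.0276) or 2 (0.0382) or fetal liver array 3 (0.0437) or 4 (0.0440), and the basophil list without bone marrow array 1 (0.0294) or 2 (0.0496) or fetal liver array 4 (0.0440).

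In Fr.B/C 6177 genes differed between the tissues, 2998 higher and 3179 lower in fetal liver, 914 of them at least 2-fold (370 and 544; 1830 with the deposited table and 2287 with the processed signals), and in 6405 (29.6%, against 2.86% by chance) the groups did not overlap. The 2.86% takes all arrays as independent and is too low for arrays that are alike within sets. With the array sets averaged and a set term 3649 genes passed, and with the scan session as a random block 5445. With median centring 20.6% of the genes that passed were higher, against 48.5%. Of the genes that passed in Fr.A and in Fr.B/C, 1481 were higher in fetal liver in both (369.83 by the product of independent lists), 1838 lower in both (549.19) and 106 opposite. Across all genes the tissue differences of the fractions correlated at r = 0.719 (rho = 0.613), and at 0.614 and 0.582 when each fraction was taken from different array sets. Genes are not independent replicates in this correlation.

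**Figure D2:**
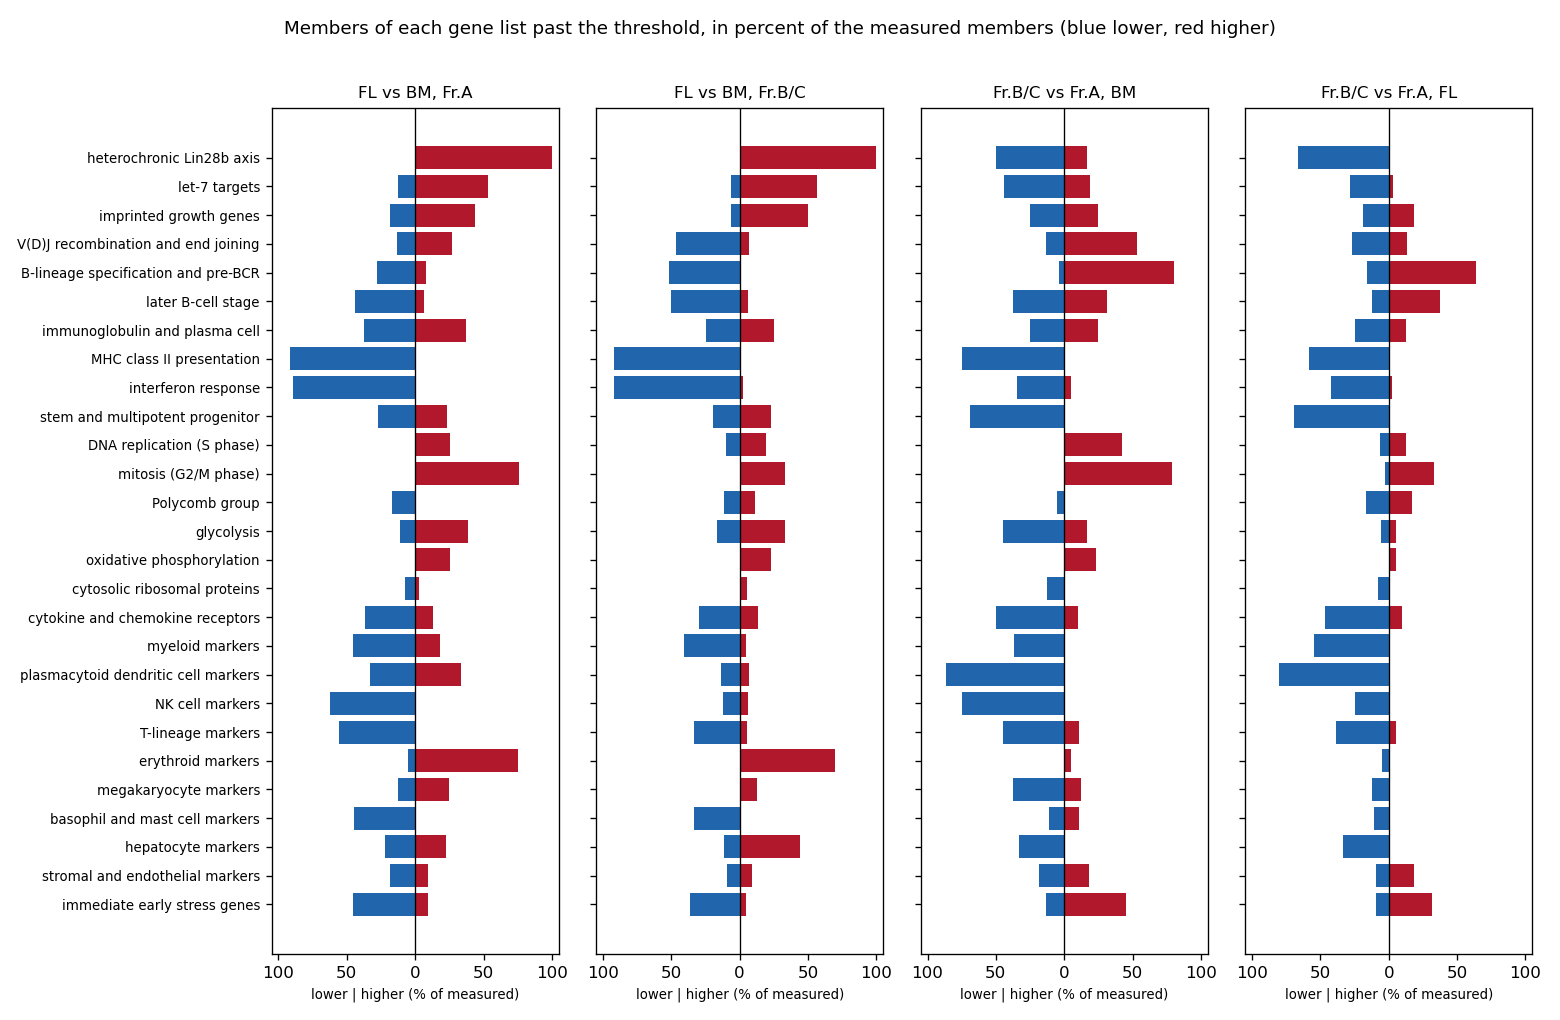
Share of the measured members of each gene list that passed, in percent, lower in blue to the left and higher in red to the right, with a panel for each comparison of 2 groups. Interferon response genes were lower in fetal liver in 34 of 38 cases in Fr.A and 35 of 38 in Fr.B/C, and the single lower erythroid gene in Fr.A is the saturated Hbb-bt, which has no direction.

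In bone marrow, the step from Fr.A to Fr.B/C came with higher B-lineage genes and lower progenitor genes. The transcription factors Spib, Irf4 and Ebf1 rose by 3.21 ± 0.12, 2.30 ± 0.09 and 0.97 ± 0.12 (SE, n = 4 and 4 arrays), and Bst1, which encodes the pro-B marker BP-3, by 2.47 ± 0.16. The stem cell gene Cd34 fell by 4.90 ± 0.19 and the cytokine receptor Flt3 by 2.96 ± 0.21. Of 25 B-lineage specification genes, 20 rose and 1 fell, also adjusted over the list alone (adjusted p = 1.36e-11, and 0.0041 with an estimated correlation). Of 26 stem and multipotent progenitor genes, 18 fell and none rose (21 fell adjusted over the list alone; adjusted p = 1.28e-09, but adjusted p = 0.0907 with an estimated correlation), including Mycn (-2.22 ± 0.20, but -0.0606 on its other probe). The adaptor Grb7 (4.55 ± 0.23), the aminopeptidase Enpep (BP-1, 4.29 ± 0.23), Slamf7 (3.73 ± 0.10) and Fcrla (3.52 ± 0.12) were among the highest changes.

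Cell cycle genes rose in bone marrow Fr.B/C. Of 33 mitotic genes 26 were higher and none lower (28 adjusted over the list alone; adjusted p = 6.78e-14, and 0.0188 with an estimated correlation), among them Ccnb2 (1.23 ± 0.13) and Ube2c (1.11 ± 0.11). Of 31 S-phase genes 13 rose and none fell (13 and 1 adjusted over the list alone; adjusted p = 0.000541, but adjusted p = 0.0912 with an estimated correlation), with Rrm2 at 1.18 ± 0.15 and Tyms at 0.98 ± 0.10. V(D)J recombination genes rose in 8 of 15 cases and fell in 2, also adjusted over the list alone (adjusted p = 0.03, but adjusted p = 0.202 with an estimated correlation and 0.0558 with the array sets averaged and a set term, and 0.0516 without Fr.A array 3). Lig4 (1.71 ± 0.20) and Xrcc6 (0.87 ± 0.15) rose, Rag1 fell (-0.65 ± 0.13, adjusted p = 0.000849, a call lost with either dye alone and with scaling between arrays) and Rag2 did not pass (-0.09 ± 0.10, adjusted p = 0.573). Over its probes Rag1 gave changes from -0.65 to -0.26. Oxidative phosphorylation genes rose in 9 of 39 cases (4 adjusted over the list alone; adjusted p = 0.00389, but adjusted p = 0.199 with an estimated correlation) and ribosomal protein genes fell in 5 of 40 (2 adjusted over the list alone; adjusted p = 0.0133, but adjusted p = 0.631 with an estimated correlation, and 0.0719 and 0.107 without Fr.A array 2 and Fr.B/C array 4). Immediate early genes rose in 10 of 22 cases and fell in 3 (10 and 4 adjusted over the list alone; adjusted p = 0.0082, but adjusted p = 0.473 with an estimated correlation), with Egr1 at 1.80 ± 0.23.

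Markers of several other lineages were lower in bone marrow Fr.B/C than in Fr.A, while the erythroid (adjusted p = 0.944), megakaryocyte (0.263), basophil and mast cell (0.925), hepatocyte (0.0528) and stromal lists (0.905) did not pass. Plasmacytoid dendritic cell markers fell in 13 of 15 cases, also adjusted over the list alone (adjusted p = 1.32e-08, and 0.0041 with an estimated correlation), among them Cox6a2 (-4.88 ± 0.22), Cd7 (-3.07 ± 0.14), the nucleic acid sensor Tlr7 (-2.14 ± 0.12) and the chemokine receptor Ccr9 (-2.10 ± 0.14). NK cell markers fell in 12 of 16 cases, also adjusted over the list alone (adjusted p = 2.22e-06, and 0.0278 with an estimated correlation), with Nkg7 at -2.64 ± 0.14 and Klrd1 at -2.57 ± 0.16. Neither list had a higher member. T-lineage markers fell in 8 of 18 cases and rose in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.00693, but adjusted p = 0.199 with an estimated correlation). Myeloid markers fell in 8 of 22, also adjusted over the list alone (adjusted p = 0.00667, but adjusted p = 0.492 with an estimated correlation), with the myeloperoxidase gene Mpo at -2.55 ± 0.34. MHC class II genes fell in 9 of 12 cases (9 lower and 1 higher adjusted over the list alone; adjusted p = 5.84e-06, but adjusted p = 0.0639 with an estimated correlation), including H2-DMb1 (-2.21 ± 0.15) and Cd74 (-1.73 ± 0.11). Cytokine receptors fell in 15 of 30 and rose in 3 (17 and 3 adjusted over the list alone; adjusted p = 6.66e-05, but adjusted p = 0.0912 with an estimated correlation). Among them Il18r1 was not well above background on any Fr.B/C array and fell at least 8.38-fold (-3.16 ± 0.16). Ly6d fell by 3.49 ± 0.20 and S100a4 by 4.40 ± 0.13. Of the Lin28b genes, Hmga2 (-4.08 ± 0.20, and -1.16 on its other probe) and Arid3a (-1.14 ± 0.12) fell, and the list did not pass (1 higher, 3 lower; adjusted p = 0.129).

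In bone marrow 7000 genes differed between the fractions, 2926 higher and 4074 lower in Fr.B/C, 1308 of them at least 2-fold (426 and 882; 2486 with the deposited table and 2821 with the processed signals), and in 6403 (29.6%, against 2.86% by chance) the fractions did not overlap. Here too the 2.86% takes all arrays as independent and is too low for arrays that are alike within sets. With the array sets averaged and a set term 4632 genes passed, and with the scan session as a fixed block 8177. Within single sessions the bone marrow arrays were too few for a test.

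In fetal liver, Fr.B/C again had higher B-lineage genes and lower progenitor genes than Fr.A. Bst1 rose by 2.33 ± 0.16 (SE, n = 4 and 4 arrays), Spib by 2.24 ± 0.13 (n = 3 Fr.B/C arrays), Irf4 by 1.62 ± 0.09 and Ebf1 by 0.54 ± 0.12 (adjusted p = 0.00452). The Ebf1 call was lost with the array sets averaged (adjusted p = 0.0967), with either dye alone and on arrays 1 and 2 alone. Cd34 fell by 4.53 ± 0.19 and Flt3 by 3.23 ± 0.21. B-lineage specification genes rose in 16 of 25 cases and fell in 4, also adjusted over the list alone (adjusted p = 1.63e-06, and 0.0274 with an estimated correlation). Stem and progenitor genes fell in 18 of 26 and none rose (19 fell adjusted over the list alone; adjusted p = 1.33e-13, and 0.0498 with an estimated correlation). Mycn fell by 1.89 ± 0.20 on its reported probe, while its other probe gave 0.0048. The alkaline phosphatase Alpl (4.17 ± 0.23), Pgm5 (3.84 ± 0.28, and 0.57 on its other probe), Enpep (3.75 ± 0.23) and Slamf7 (3.19 ± 0.10) rose most among the genes named in this paragraph.

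Between the fetal liver fractions, 4 of the 6 Lin28b genes were lower in Fr.B/C. Igf2bp2 (-2.45 ± 0.11), Hmga2 (-2.30 ± 0.20), Igf2bp3 (-1.06 ± 0.22) and Arid3a (-0.99 ± 0.12) fell, while Lin28b (0.26 ± 0.15, adjusted p = 0.267) and Igf2bp1 (0.21 ± 0.14, adjusted p = 0.361) did not pass. The Igf2bp3 call was lost with the array sets averaged (adjusted p = 0.102) and with either dye alone. The list passed, with the same count adjusted over the list alone (adjusted p = 0.00303, but adjusted p = 0.095 with an estimated correlation). Let-7 targets fell in 9 of 32 cases and rose in 1 (9 and 4 adjusted over the list alone; adjusted p = 0.0339, but adjusted p = 0.121 with an estimated correlation and 0.0981 with the replicate number as a block). That call was also lost without Fr.A array 3 (0.0550), Fr.B/C array 1 (0.0510) or Fr.B/C array 2 (0.0629). Ccnd1, which is among them, fell by 3.28 ± 0.08. Mitotic genes rose in 11 of 33 cases and fell in 1 (17 and 1 adjusted over the list alone; adjusted p = 4.47e-05, but adjusted p = 0.15 with an estimated correlation), with Plk1 at 0.72 ± 0.11 and Ccnb1 at 0.61 ± 0.10. S-phase genes rose in 4 of 31 and fell in 2, also adjusted over the list alone (adjusted p = 0.0204, but adjusted p = 0.246 with an estimated correlation, and 0.0732 without Fr.B/C array 1), with Tyms at 0.75 ± 0.10. The call of Ccnb1 was lost with Cy5 alone, and those of Plk1 and Tyms with Cy3 alone. Immediate early genes rose in 7 of 22 and fell in 2 (10 and 2 adjusted over the list alone; adjusted p = 0.0046, but adjusted p = 0.422 with an estimated correlation), with Egr1 at 1.81 ± 0.23. Rag1 fell by 1.07 ± 0.13, and Rag2 by 0.45 ± 0.10 (adjusted p = 0.00384), a call lost with the array sets averaged, with or without a set term, or as a random block without it, with Cy3 alone, scaling between arrays and on arrays 1 and 2 alone.

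Markers of several other lineages fell here too, while the erythroid (adjusted p = 0.957), megakaryocyte (0.0958), basophil and mast cell (0.371), hepatocyte (0.273) and stromal lists (0.77) did not pass. Plasmacytoid dendritic cell markers were lower in 12 of 15 cases (13 adjusted over the list alone; adjusted p = 1.33e-13, and 0.000878 with an estimated correlation), among them the transcription factors Runx2 (-5.17 ± 0.23) and Irf8 (-1.63 ± 0.08), Ccr9 (-3.75 ± 0.14) and Cd7 (-1.90 ± 0.14). Myeloid markers fell in 12 of 22 cases, also adjusted over the list alone (adjusted p = 1.02e-05, but adjusted p = 0.258 with an estimated correlation), including Mpo (-2.80 ± 0.34) and the growth factor receptor Csf1r (-2.62 ± 0.13, to -0.10 over its probes). NK cell markers fell in 4 of 16, also adjusted over the list alone (adjusted p = 0.0229, but adjusted p = 0.246 with an estimated correlation). Klrd1, not well above background on any Fr.B/C array, fell at least 7.70-fold (-2.96 ± 0.16), and Nkg7 fell by 2.15 ± 0.14. None of these lists had a higher member. T-lineage markers fell in 7 of 18 cases and rose in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.00306, but adjusted p = 0.171 with an estimated correlation). Interferon response genes fell in 16 of 38 and rose in 1, also adjusted over the list alone (adjusted p = 1.45e-06, and 0.0274 with an estimated correlation), for example Rtp4 (-1.65 ± 0.14) and Ifi203 (-1.63 ± 0.12). MHC class II genes fell in 7 of 12 (8 lower and 1 higher adjusted over the list alone; adjusted p = 4.47e-05, but adjusted p = 0.0884 with an estimated correlation), including H2-DMb1 (-2.66 ± 0.15) and H2-Aa (-1.91 ± 0.17, and -0.60 on its other probe). Ly6d, a member of the B-lineage specification list, fell by 3.36 ± 0.20. Cytokine receptors fell in 14 of 30 and rose in 3 (17 and 3 adjusted over the list alone; adjusted p = 4.3e-06, but adjusted p = 0.07 with an estimated correlation), and ribosomal proteins fell in 3 of 40 (2 adjusted over the list alone; adjusted p = 0.0173, but adjusted p = 0.646 with an estimated correlation, and 0.0844 and 0.0867 without Fr.A arrays 3 and 4).

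In fetal liver 4928 genes differed between the fractions, 2159 higher and 2769 lower in Fr.B/C, 908 of them at least 2-fold (332 and 576; 1665 with the deposited table and 2041 with the processed signals), and in 5231 (24.2%, against 2.86% by chance) the fractions did not overlap. Again the 2.86% takes all arrays as independent and is too low for arrays that are alike within sets. With the array sets averaged and a set term 2862 genes passed, and with the scan session as a fixed block 6848. Each fetal liver session held arrays 1 and 2, or 3 and 4, of both fractions, and gave 4077 and 9135 genes on its own. With the session as a block 14 of the 15 lists that passed were kept, all but let-7 targets (adjusted p = 0.0857). The fits to arrays 1 and 2 and to arrays 3 and 4 kept 13 and 10 lists. The mean change in fetal liver was 0.72 and 0.66 for B-lineage genes and -1.16 and -1.15 for stem cell genes. It was -1.03 and -1.08 for Lin28b genes and 0.40 and 0.18 for mitotic genes. Arrays 1 and 2 lost let-7 targets (0.0952) and ribosomal proteins (0.552). Arrays 3 and 4 lost let-7 targets (0.156), mitotic (0.0574) and S-phase genes (0.125) and NK cell (0.141) and T-lineage markers (0.0898). With median centring 31.8% of the genes that passed were higher, against 43.8%. In both tissues 1419 genes were higher in Fr.B/C (292.19 by the product of independent lists), 1901 lower (521.78) and 68 opposite. The fraction differences of the tissues correlated across genes at r = 0.729 (rho = 0.602), and genes are not independent replicates.

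The change from Fr.A to Fr.B/C differed between fetal liver and bone marrow for 1612 genes, 961 with a higher and 651 with a lower change in fetal liver. Among the Lin28b genes, Igf2bp2 fell further in fetal liver (interaction -1.74 ± 0.16, adjusted p = 1.23e-05), and Igf2bp3 fell there while it rose in bone marrow (-1.06 and 0.94; interaction -1.998 ± 0.32, adjusted p = 0.0011). All 3 of these Igf2bp3 calls were lost with the array sets averaged (adjusted p = 0.102, 0.101 and 0.171) and with either dye alone. Over its probes Igf2bp3 ran from 0.37 to 0.94 in bone marrow, from -1.06 to -0.72 in fetal liver and from -1.998 to -1.19 for the interaction. Ccnd1 fell by 3.28 in fetal liver and by 1.07 in bone marrow (interaction -2.21 ± 0.11, adjusted p = 8.75e-08). Lin28b (0.26 ± 0.22, adjusted p = 0.548) and Arid3a (0.14 ± 0.18, adjusted p = 0.712) did not pass. The reported probe of Hmga2 gave an interaction of 1.78 ± 0.28 (adjusted p = 0.00107) and its other probe -2.31, so its direction is not settled.

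The interaction of NK cell markers was higher in 7 of 16 cases and lower in none (9 adjusted over the list alone; adjusted p = 0.000391, but adjusted p = 0.0967 with an estimated correlation), including Ccl5 (2.34 ± 0.43), Tbx21 (1.08 ± 0.14) and Txk (0.95 ± 0.15, and 0.07 on its other probe). Only 4 of the 16 were well above background in every group and 10 were already lower in fetal liver Fr.A, so a smaller fall there is not shown apart from the background level. Il18r1 fell by 3.16 in bone marrow, while its change in fetal liver, -0.44, did not pass (interaction 2.72 ± 0.23). Cxcr6 (2.56 ± 0.27), the scavenger receptor Cd163 (2.35 ± 0.17), Cd74 (1.27 ± 0.15) and H2-Eb1 (1.01 ± 0.25) went the same way. In fetal liver Fr.B/C Il18r1, Cxcr6, Ccl5 and Txk were not well above background on any array, and Cd163 was on only 1. In bone marrow Fr.B/C Il18r1 was on no array and Cxcr6 on only 1. The sizes of these interactions are not settled. Mitotic genes had a lower interaction in 6 of 33 cases and a higher one in none (10 adjusted over the list alone; adjusted p = 2.86e-08, but adjusted p = 0.0967 with an estimated correlation), with Ube2c at -0.71 ± 0.16. B-lineage specification genes were lower in 5 of 25 cases (6 adjusted over the list alone; adjusted p = 2.82e-05, but adjusted p = 0.0967 with an estimated correlation), including Spib (-0.97 ± 0.17). V(D)J genes were lower in 3 of 15 (7 adjusted over the list alone; adjusted p = 0.000391, but adjusted p = 0.0967 with an estimated correlation), including Lig4 (-1.15 ± 0.28) and Xrcc6 (-1.0045 ± 0.22). Interferon response genes were lower in 7 of 38 and higher in 3 (11 and 4 adjusted over the list alone; adjusted p = 0.000887, but adjusted p = 0.0979 with an estimated correlation). No oxidative phosphorylation gene passed, though that list did (adjusted p = 0.0423, but adjusted p = 0.539 with an estimated correlation, 0.134 with the scan session as a block, and 0.0515 to 0.237 without any 1 of 9 arrays).

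The genes with the lowest interaction included Grb7 (-2.59 ± 0.32), which rose by 4.55 in bone marrow and 1.95 in fetal liver, Rasgrp3 (-2.33 ± 0.16), Rab6b (-2.23 ± 0.17), Adamts7 (-2.23 ± 0.24) and Runx2 (-2.24 ± 0.33). Irf8 (-1.12 ± 0.12) and Csf1r (-1.58 ± 0.19, from -1.58 to 0.06 over its probes) were lower as well. Pgm5 (2.33 ± 0.39, and 0.44 on its other probe) and Cox6a2 (2.30 ± 0.31) were higher. The number of interaction genes moved with the model, from 1612 to 251 with the array sets averaged and a set term (250 of them among the 1612), 3522 with the replicate number as a block, 3224 with the scan session as a block, 421 with median centring and 1040 with the processed signals. Of 36 interaction calls of genes named in the text, 26 were kept with the array sets averaged and a set term. Those of Ccl5, Ccnb2, Cd7, H2-Eb1, Irf4, Slamf7, Spib, Txk, Ube2c and Xrcc6 were lost. Without the set term 8 of the 36 were kept, those of Ccnd1, Igf2bp2, Rasgrp3, Rab6b, Il18r1, Cd163, Csf1r and S100a4. With Cy5 or Cy3 alone 6 and 4 were kept. Median centring kept 24, and lost Irf8, Lig4, S100a4, Zap70, Ccnb2, H2-Eb1, Irf4, Spib, Ube2c, Xrcc6, Slamf7 and Cd7. The processed signals kept 28, and lost Adamts7, Ccl5, Pgm5, Rab6b, Ccnb2, H2-Eb1, Slamf7 and Cd7. The interaction call of H2-Eb1 was also lost without bone marrow Fr.B/C array 3 or 4 (adjusted p = 0.0522 and 0.0502), fetal liver Fr.A array 3 or 4 (0.0536 and 0.0517) or fetal liver Fr.B/C array 4 (0.0527).

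**Figure D3:**
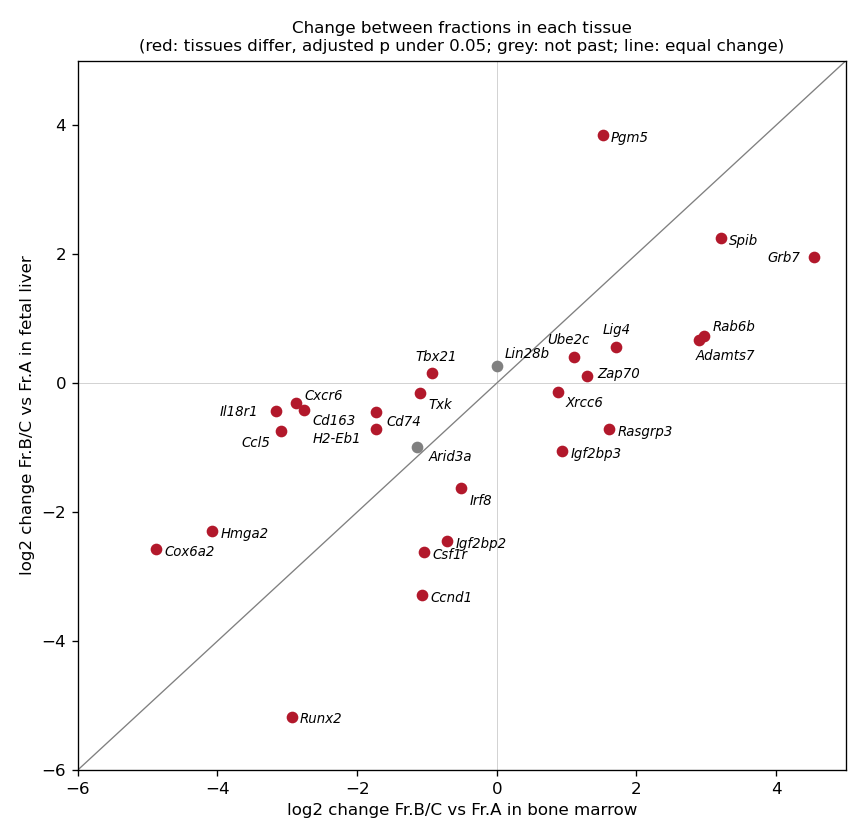
Log2 change from Fr.A to Fr.B/C in bone marrow (horizontal) against that in fetal liver (vertical) for named genes, in red where the tissues differed at an adjusted p under 0.05 and in grey where they did not, with a line of equal change. Grb7 lies at 4.55 in bone marrow and 1.95 in fetal liver, Ccnd1 at -1.07 and -3.28, and the direction of Hmga2 is not settled between its probes.

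Sex-linked genes were used to check the labels, which describe the bone marrow donors as female and give no sex for the embryos. Xist, expressed from the inactive X chromosome, was lower in fetal liver Fr.A (-1.80 ± 0.30, adjusted p = 0.00032) and in bone marrow Fr.B/C against Fr.A (-1.12, adjusted p = 0.00934), and did not pass between the tissues in Fr.B/C (-0.64, adjusted p = 0.129). Its probes gave changes from -1.80 to -0.12 in fetal liver Fr.A and from -1.12 to -0.05 in bone marrow. The Y-linked Eif2s3y, Ddx3y and Kdm5d passed in no comparison without a block or array weights on all arrays, and were well above background on all 16 arrays, those of the bone marrow sorts included. On bone marrow Fr.A arrays 1 and 2 they were higher than on arrays 3 and 4 by 1.82, 1.92 and 1.03, and in Fr.B/C by 1.31, 1.68 and 1.32. Leaving out bone marrow array 1 made Xist pass in Fr.B/C (adjusted p = 0.0492) and, when it was the Fr.A array, for the interaction (0.0215). Kdm5d passed in Fr.A without array 2 of bone marrow (0.0463) or of fetal liver (0.0395). With the replicate number as a block Eif2s3y rose (0.68 in bone marrow and 0.48 in fetal liver; adjusted p = 0.00057 and 0.00781) and Ddx3y fell (-0.43 and -0.66; adjusted p = 0.00884 and 0.00075) between the fractions, and Xist passed in Fr.B/C (adjusted p = 0.0351) and for the interaction (adjusted p = 0.00097). With array weights all 3 Y-linked genes were higher in fetal liver Fr.A (Ddx3y 0.0464, Eif2s3y 0.0163 and Kdm5d 0.000879). The Xist call in Fr.A was lost with Cy5 alone (0.0864) and scaling (0.0943), and that in bone marrow with the processed signals (0.139), the deposited table (0.0609), Cy5 alone (0.211), scaling (0.69) and array sets averaged (0.106).

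**Figure D4:**
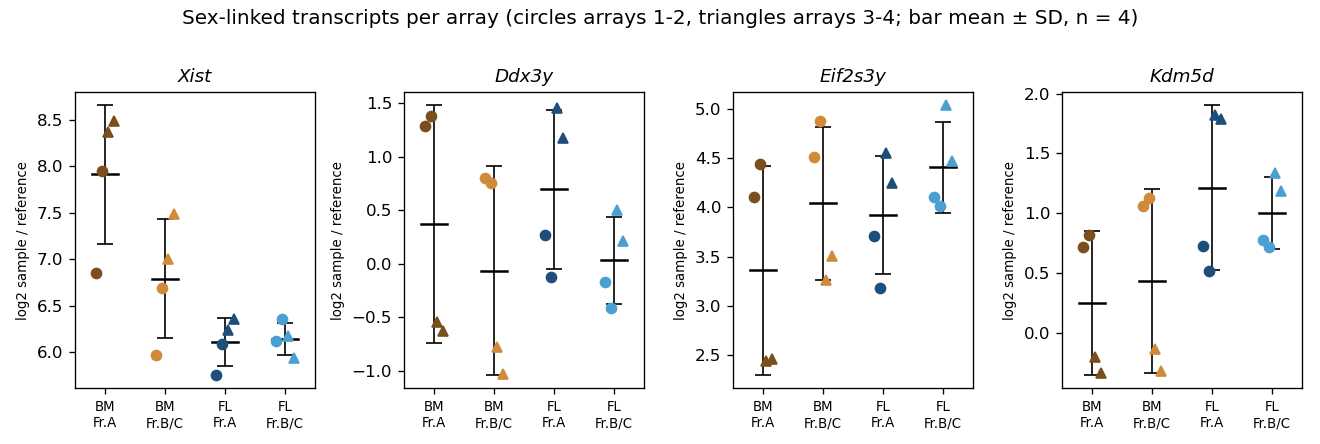
Log2 sample over reference of Xist and of the Y-linked Ddx3y, Eif2s3y and Kdm5d in the 4 groups, with a circle for each of the arrays 1 and 2, a triangle for each of the arrays 3 and 4, and bars at the mean ± SD (n = 4 arrays). In bone marrow Fr.A, Eif2s3y lay 1.82 higher on arrays 1 and 2 than on arrays 3 and 4, with the opposite order in fetal liver (-0.95).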

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

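In this part the tests of scan session, of the reference behind the array sets, of the homologues in the sample channel, of male-cell RNA, and the control for the dye-swap test were chosen only after the result was seen.

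Were the 4 arrays of a group independent, the splits would exclude chance for the number of genes between the tissues and for the interaction. The arrays were alike within sets, so that condition was not met. In each of the 5 comparisons, 1 of the 35 splits of the samples into groups of the same sizes, the real one, gave as many genes. Fetal liver against bone marrow gave 6402 genes in Fr.A (highest of the other splits 77) and 6177 in Fr.B/C (405). Fr.B/C against Fr.A gave 7000 in bone marrow (672) and 4928 in fetal liver (515). For the interaction the splits were made on the differences between the fractions of each sort, on which the real split gave 2699 genes and the highest of the others 28. In every comparison the highest of the other splits kept arrays 1 and 2 together and arrays 3 and 4 together. Since the arrays of such a set were alike, whatever the cause, only the 2 other splits that keep the sets compare like with like. These are too few for a share under 0.05. By the labels, numbers pair the samples only between the fractions of a tissue, though arrays of the same number also deviated together across the tissues in Fr.B/C (r = 0.276 to 0.480). Between the fractions the 7 other splits that parted every number, as the real split does, gave at most 4 genes in bone marrow and no more in fetal liver, while the highest split parted no number. With the fractions paired only these 7 compare like with like, too few for a share under 0.05. Chance is therefore not excluded by the splits in any of the 5 comparisons.

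Single arrays stood far from the other 3 of their group in 18 of 429 groups of values tested (4.20%), near the 1 in 20 that chance gives. In bone marrow Fr.A, array 1 had log2 ratios of -2.20 for Ccnd1 (others -2.45 to -2.42) and 1.66 for Irf8 (1.51 to 1.53). In bone marrow Fr.B/C, array 3 stood apart for Adamts7 (3.74, others 3.13 to 3.16), Ifi47 (2.27, others 2.62 to 2.64) and Psmb8 (0.33, others 0.20 to 0.21), and array 4 for Tyms (0.73, others 0.18 to 0.19) and Ube2c (0.49, others 0.03 to 0.10). In fetal liver Fr.A, array 1 stood apart for Cd163 (0.49, others 0.02 to 0.05), array 2 for Alpl (-3.55, others -3.19 to -3.12) and H2-DMb1 (1.65, others 1.07 to 1.16), and array 3 for Blk (0.96, others 0.63 to 0.69) and Ccr9 (1.75, others 1.47 to 1.51). In fetal liver Fr.B/C, array 1 stood apart for Adamts7 (1.38, others 1.102 to 1.126) and Rps4l (6.34, others 5.66 to 5.74), array 3 for Oas1a (-0.57, others -0.72 to -0.70) and array 4 for Txk (-0.52, others -0.88 to -0.82). Array 3 of that group also had 52.9% of probes well above background (others 58.7% to 59.0%) and 205 rejected spots (others 3 to 31).

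The change from Fr.A to Fr.B/C differed between the tissues in 1612 genes (7.46% of those tested), and in 36 of the 67 genes that the text names for the fractions. The 67 include genes that the naming rule took by their interaction, so their share is raised by that choice. The interaction, fetal liver change minus bone marrow change, was above 0 for Il18r1 (2.72), Cxcr6 (2.56), Cd163 (2.35), Ccl5 (2.34), Pgm5 (2.33), Cox6a2 (2.30), Alpl (1.89), Hmga2 (1.78), S100a4 (1.61), Itgb7 (1.51), Cd74 (1.27), Cd7 (1.17), Tbx21 (1.08), H2-Eb1 (1.01) and Txk (0.95). It was below 0 for Grb7 (-2.59), Rasgrp3 (-2.33), Runx2 (-2.24), Adamts7 (-2.23), Rab6b (-2.23), Ccnd1 (-2.21), Igf2bp3 (-1.998), Igf2bp2 (-1.74), Fcrla (-1.69), Ccr9 (-1.65), Csf1r (-1.58), Zap70 (-1.19), Rtp4 (-1.15), Lig4 (-1.15), Irf8 (-1.12), Xrcc6 (-1.0045), Spib (-0.97), Ube2c (-0.71), Irf4 (-0.68), Ccnb2 (-0.66) and Slamf7 (-0.55). Il18r1, Cxcr6, Ccl5, Txk and Cd163 were not well above background on most or all fetal liver Fr.B/C arrays, so these values are not measured sizes. The sign of Hmga2 turned when its probes were averaged (-0.26). The call of Ccnb2 was lost without any 1 of the arrays other than bone marrow Fr.A 1, fetal liver Fr.A 3 and fetal liver Fr.B/C 1 and 2 (adjusted p = 0.0514 to 0.101), that of H2-Eb1 without bone marrow Fr.B/C array 3 or 4, fetal liver Fr.A array 3 or 4 or fetal liver Fr.B/C array 4 (0.0502 to 0.0536), and that of Slamf7 without bone marrow Fr.A array 2 or 4, bone marrow Fr.B/C array 1 or 2, fetal liver Fr.A array 1, 2 or 4 or fetal liver Fr.B/C array 3 or 4 (0.0516 to 0.0797).

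Arrays 1 and 2 of a group resembled each other, as did arrays 3 and 4: in 7 of 8 such sets the SD of the difference was smaller within the set than for every pair across sets, all but arrays 1 and 2 of fetal liver Fr.A (0.318, lowest across sets 0.302). In bone marrow, arrays of a set scanned in different sessions differed by an SD of at most 0.231 and arrays of different sets by at least 0.293. A shared scan session is therefore not what made those arrays alike. No session held arrays of both sets of a bone marrow fraction, so a batch that spans several sessions is not excluded. Each fetal liver set had its own session. A difference in the reference may be part of the cause, since it carried 0.479 to 0.589 of the variance of the set difference, and that difference in the reference channel was alike in all groups (r = 0.625 to 0.873, against -0.123 to 0.329 in the sample channel). Whether it is the whole cause stays open, and so does whether the arrays of a set are dye-swapped labels of 1 RNA or the separate sorts that the labels describe. The difference between the arrays of a set was shared by the fractions at r = 0.478 to 0.658, beyond the bound set in advance for separate sorts, but a control that paired arrays of unlike numbers gave 0.369 to 0.615, so these explanations cannot be told apart.

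Bone marrow sorts described as female gave signal on Y-linked probes: Eif2s3y, Ddx3y and Kdm5d were well above background on all 8 arrays and higher on arrays 1 and 2 than on 3 and 4, by 1.82, 1.92 and 1.03 in Fr.A and 1.31, 1.68 and 1.32 in Fr.B/C, while Xist was lower (-1.03 and -0.92). Cross-hybridisation with X-linked homologues is excluded as the cause of this difference between the sets, since in the sample channel, where it would act, no homologue rose with its partner (largest share -0.0423). It is not excluded as a source of the signal common to all 8 arrays, because a constant part leaves no difference between the sets. The log ratios of the homologues went both ways (Ddx3x 0.73 and 0.72, Kdm5c -0.49 and -0.61), so their mean of 0.0125, against 1.51 for the Y-linked genes, decides nothing. A difference in the reference is excluded as the cause of the difference between the sets for these genes as well (-0.00751 in the reference channel). RNA of male cells in the sorts behind arrays 1 and 2 stays open as a candidate explanation that no value here tests, since the smallest Y-linked difference (1.03) only restates the pattern. In fetal liver the same genes were lower on arrays 1 and 2, with differences of -0.95, -1.24 and -1.19 in Fr.A and -0.69, -0.65 and -0.52 in Fr.B/C.

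Erythroid transcripts were higher in fetal liver in both fractions, with a median change over the list of 1.59 in Fr.A and 1.53 in Fr.B/C. Within-array normalization is excluded as the cause, since the medians stayed at 1.41 and 1.31 with median centring. RNA of erythroid cells carried over in the sorts is a candidate explanation: the erythroid genes deviated from their group means together over the fetal liver arrays (median pairwise r = 0.927, 95th percentile of matched random lists 0.172), and the probe of Hbb-bt was saturated on all 8 fetal liver arrays. A sort for B-lineage surface markers would remove such cells, though not RNA released from them. Of the 20 genes, 13 were well above background on all bone marrow arrays too and 0 belong to another list, and expression in the fetal B-lineage cells themselves, a difference of tissue, stays open and untested.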

How the results depend on the processing

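The fits with array sets averaged, blocked or taken alone, and scaling and quantile normalization between arrays, were tests chosen only after the result was seen. The 5 gene counts (6402 and 6177 between the tissues in Fr.A and in Fr.B/C, 7000 and 4928 between the fractions of bone marrow and of fetal liver, 1612 for the interaction) are given in that order. They stayed within 1.5 times their value with no background subtraction, the deposited table, quantile normalization, either other filter on dim probes, no dye term, every probe tested, the mean over probes, trended and robust empirical Bayes, scan session as a random block (run for the tissue comparisons only) and the set as a random block with a set term. Leaving out each array in turn gave 5300 to 6188, 4854 to 5843, 6084 to 6640, 4018 to 5135 and 1158 to 1669. Stricter thresholds lower the counts by construction. At an adjusted p under 0.01 they were 4159, 3840, 3201 in fetal liver and 695 for the interaction. At least 2-fold change left 1.0e+03 genes (311 higher and 694 lower), 914, 1308, 908 and 452, and 452 of the 3319 genes shared by the tissue comparisons. These 2-fold counts were higher with the deposited table (2028, 1830, 2486, 1665, 907) and the processed signals (2312, 2287, 2821, 2041, 803), and that of the interaction was lower with median centring (263), sets averaged (45, with a set term 237), Cy5 (32) or Cy3 alone (10) and higher on arrays 3 and 4 alone (1052). The cause was not tested.

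The counts fell with Cy5 alone (2263, 1645, 2678, 1690, 32), Cy3 alone (2078, 1512, 2684, 1268, 10) and each set averaged (2444, 1934, 3285, 1786, 45; with a set term 3934, 3649, 4632, 2862, 251). The set as a random block, which counts likeness within sets, gave 3898, 3530, 4539, 2939 and 492. Arrays 1 and 2 alone gave 714 interaction genes, while arrays 3 and 4 alone gave more than all arrays (10015 in Fr.A, 9135 in fetal liver, 6747 for the interaction). Median centring gave 4041 in Fr.A, 4099, 2635 and 421 genes (4204 in Fr.B/C stayed within 1.5 times) and array weights 8836 in fetal liver and 3378 for the interaction. The interaction moved also with the processed signals (1040), scaling (915), scan session as a block (3224), the sort as a random block (3117) and the set as a fixed block (3749). Cy5 alone keeps 1 array of each set per group, while arrays 1 and 2 or 3 and 4 alone keep both of 1 set. In Fr.A these gave 2263, 5745 and 10015 genes from 2 arrays per group, so the number of arrays does not account for the difference. In simulated data with no changed gene and a set effect of its own in each group, the main model gave 27 to 119 false calls. Counts that take the arrays of a set as independent may thus be too high. Beyond this, the cause of the counts from Cy5 alone onward was not tested.

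With the replicate number as a block the interaction rose to 3522 genes. That block keeps the pairing of the fractions in the fraction comparisons and the interaction only. Between the tissues it is an effect of the number shared by bone marrow and fetal liver, which share no animals. Changes of calls between the tissues with this block do not come from that pairing. Among the lists, myeloid (adjusted p = 0.016) and basophil markers (0.0465) passed in Fr.A, basophil markers passed (0.0355) and hepatocyte markers were lost (0.0577) in Fr.B/C, and let-7 targets were lost in fetal liver (0.0981). The basophil list of Fr.A did not pass with the array sets averaged, with or without a set term. Of the genes the naming rule took, 48 calls were gained, for example Il7r in Fr.B/C (-0.41, 0.00816). No other call of a list or of a gene the rule took changed. Over all genes the block kept 6388, 6161, 6971, 4919 and 1612 of the calls.

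Of the genes named in the text with a call, array sets averaged with a set term kept 39 of 39, 40 of 41, 43 of 43, 40 of 41 and 26 of 36, without that term 37 of 39, 37 of 41, 41 of 43, 38 of 41 and 8 of 36, and Cy5 or Cy3 alone 6 and 4 of the 36. With the term Rag2 was lost between the tissues in Fr.B/C and between the fetal liver fractions, and Ccl5, Ccnb2, Cd7, H2-Eb1, Irf4, Slamf7, Spib, Txk, Ube2c and Xrcc6 for the interaction. Without it Ebf1 and Rhd were lost in Fr.A, Klf1, Rag1, Rag2 and Rhd in Fr.B/C, Igf2bp3 and Xist in bone marrow, and Ebf1, Igf2bp3 and Rag2 in fetal liver. Of the 62 list calls 23 held with an estimated correlation, and the fry test passed 88 of 135.

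Among results past the threshold as reported or with the other setting, direction turned in 11 cases, and the cause was not tested. Turns of results that passed in neither were not counted. With the processed signals the interaction of Dlk1 was 0.56. With median centring the mean change of ribosomal protein genes was 0.19 between the tissues in Fr.B/C and 0.0027 in fetal liver, and with quantile normalization their interaction was -0.0930. By camera that list passed in the turned direction in Fr.B/C (adjusted p = 5.5e-05) and for the interaction (0.0244), but not in fetal liver (0.512). With the mean over probes the interaction of Hmga2 was -0.26. On arrays 1 and 2 alone fetal liver was lower in Ddx3y (-1.26 in Fr.A, -1.07 in Fr.B/C) and Eif2s3y (-0.83), and on arrays 3 and 4 alone Car2 fell in fetal liver (-0.32). Imprinted genes, with mean changes of -0.13 in bone marrow and -0.0697 in fetal liver, passed as lower with fry, while camera put them higher without passing.

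Aquantile moves no log ratio by construction and counts in no tally. The list test was not run with random blocks, which camera does not take, or with every probe tested. Signal over background was the limit for dim genes: 52.9% to 68.3% of probes were well above background on an array, and below it a fold is a bound or was not detectable at this depth.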

Other observations

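In this part the fits with array sets averaged were the only tests chosen after the result was seen.

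Several genes outside the lists marked the step from Fr.A to Fr.B/C in both tissues. Jhy rose by 4.03 in bone marrow and 3.67 in fetal liver, Smtnl2 by 3.64 and 3.20, and the lymphocyte adaptor gene Sit1 by 3.44 and 3.17, while the transporter gene Slc35d3 fell by 3.93 and 3.81. All 4 were well above background on every array, and none passed for the interaction (adjusted p = 0.349 for Jhy, 0.135 for Smtnl2, 0.46 for Sit1 and 0.82 for Slc35d3). The integrin gene Itgb7 fell by 3.93 in bone marrow and by 2.41 in fetal liver (interaction 1.51).

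The kinase gene Zap70, on the list of T-lineage markers, rose by 1.30 in bone marrow Fr.B/C, while its change in fetal liver (0.11) did not pass. Its interaction (-1.19 ± 0.16, adjusted p = 0.000366) was lost with median centring (0.0511), array sets averaged without a set term (0.0573), Cy5 alone (0.111) and Cy3 alone (0.156), and Zap70 was lower in fetal liver Fr.B/C by a log2 change of -1.73 ± 0.12 (adjusted p = 2.14e-08). The transcription factor gene Bach2, on the list of B-lineage genes, was lower in fetal liver in both fractions (-1.31 ± 0.20 and -1.75 ± 0.20, adjusted p = 0.000114 and 7.4e-06). Rps4l, a paralogue of a ribosomal protein gene, was higher in fetal liver Fr.A by 3.03 ± 0.15 (adjusted p = 1.29e-09), while the list of ribosomal protein genes did not pass there (adjusted p = 0.21), though it did, lower in fetal liver, with array sets averaged (0.0350).

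Several lists did not pass between the fractions. In bone marrow glycolysis genes rose in 3 of 18 cases and fell in 8 (adjusted p = 0.642), genes of later B-cell stages rose in 5 of 16 and fell in 6 (0.849), and imprinted genes rose in 4 of 16 and fell in 4 (0.905). In fetal liver V(D)J recombination genes rose in 2 of 15 and fell in 4 (0.753), and oxidative phosphorylation genes rose in 2 of 39 (0.371). Erythroid genes rose in 1 of 20 in bone marrow (0.944) and fell in 1 of 20 in fetal liver (0.957).

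Leaving out 1 array made some further lists pass. In bone marrow these were interferon response genes (0.108 with all arrays) without Fr.A array 4 (0.0450), let-7 targets (0.0694) without Fr.B/C array 2 (0.0411), and hepatocyte markers (0.0528) without Fr.A array 2 (0.0306) or 4 (0.0459) or Fr.B/C array 1 (0.0384) or 3 (0.0480). In fetal liver megakaryocyte markers (0.0958) passed without Fr.B/C array 4 (0.0354). For the interaction myeloid markers (0.173) passed without bone marrow Fr.A array 3 (0.0196), bone marrow Fr.B/C array 1 (0.0408) or fetal liver Fr.B/C array 3 (0.0408).

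Saturation touched few calls: the lower group was saturated in 4 of the 6402 genes in Fr.A and 2 of the 6177 in Fr.B/C between the tissues, and both groups in 5 and 6.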
